A study of Mus musculus with 31 samples.

How the data were processed

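RNA from liver, kidney and circulating white blood cells of male C57BL/6J mice given lipopolysaccharide (LPS) together with vehicle, IVIg or modified IVIg (modIVIg) was measured on Illumina mouse BeadChip arrays with 25697 probes, 1 array per sample. Groups and replicate numbers were taken from the sample titles. Each array was treated as a separate animal's sample. If arrays of a group shared an animal, the p values would measure only the spread between preparations. The labels do not say whether arrays of different organs with the same replicate number come from the same mouse. The main test of differences between organs treats them as independent.

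The deposited bead signals are intensity values per probe and array, read by the authors with GenomeStudio 1.9.0, neither normalised between arrays nor background subtracted. The deposited detection p value per probe and array was made by the scanner software, per the file headers, from the signal against negative control beads, before any normalisation by the authors. The authors' processed table holds log2 values, normalised among the arrays of each organ according to the series text; lumi and limma are named in the authors' processing notes without their roles, and the method of normalisation is not stated. On 30 arrays the authors' column was a strictly increasing function of that array's bead signal.

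The bead signals of blood modIVIg replicate 2 stayed at background. Only 0.712% of its probes were detected at a detection p under 0.01, and its Spearman correlation across probes with the authors' column for the same sample was 0.005. This array was left out, so 30 of 31 arrays were analysed. On the others the share of probes detected was 31.6% to 35.3% in liver, 34.8% to 41.2% in kidney and 8.09% to 18.7% in blood. The number of arrays limits the precision of every value.

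Bead signals of each organ were background corrected and quantile normalised with neqc of limma 3.58.1 (offset 16) in R 4.3.3. A probe was kept when its detection p was under 0.01 on at least as many arrays as the smallest group of the organ (4 in liver, 3 in kidney and 2 in blood, counting the array left out). Of the 25697 probes, 23978 had 1 gene symbol, 0 had several and 1719 had none; 23962 matched a current Entrez entry, and no symbol changed. Each gene was represented by its kept probe with the highest mean, and probes without a symbol were tested but not named. This left 7155 features in liver, 8544 in kidney and 3975 in blood. Genes were tested with limma (lmFit, eBayes), with the 3 treatment groups of an organ sharing 1 estimate of the spread, and Benjamini-Hochberg adjusted p under 0.05 as the threshold. Differences of a change between organs were tested with limma's F test in a fit of 9 groups over 3329 features kept in every organ. The lone usable blood modIVIg sample was assumed to vary like the other blood groups. Values after ± are standard errors of the fitted log2 change unless SD is written. Where no array of a group detected a probe, the fold is a lower bound against the lowest detected signal of each array of that group, or the probe's own signal where that was higher.

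Before the data were examined, 47 gene lists (pathways and cell type markers) were written down with the organs they apply to, together with the tests, the comparisons and the rule for naming genes. A list with at least 5 measured members was tested with limma's camera at its preset correlation of 0.01, and Benjamini-Hochberg adjustment ran over the lists of the same organ and comparison. The rule names the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap, members of lists that passed over all genes or over their list, and up to 4 leading members of a list past its own test. Where fewer than 5 genes passed, the 3 highest and 3 lowest by limma's moderated statistic are named as not passed.

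Alternatives covered the background correction, the authors' values, the detection filter, the probe per gene, joint normalisation of all arrays, array quality weights, the variance prior, the samples in the fit, the replicate number as a block, an estimated correlation for the lists, and each array left out in turn. Chosen after seeing the data were a block for a split of the kidney arrays, fits within each part of that split, the mean of the adipocyte markers as a covariate in kidney, the blank blood array kept, and a fit of liver and kidney only. The simulations and splits for shared leading features in liver were also chosen then. A block for the slide was not run, because the files name no slides. In kidney, same-numbered arrays of different treatments deviated together in all 10 pairs (correlations across genes from 0.587 to 0.849). This pairing comes from the data, through a split of replicates 1 and 2 from replicates 3 and 4, and not from the labels. The main kidney fit does not use it. Kidney values come from that fit unless a block, a part of the split or the covariate is named. Results with the replicate number as a block are given separately. The pipeline was tested on simulated data: at a log2 change of 1 it recovered 77.3% of the changed genes in the liver comparison of modIVIg with vehicle, 28.4% in the kidney comparison of IVIg with vehicle and 4.69% in the blood comparison of IVIg with vehicle. At a log2 change of 2 it recovered 0% in the blood comparison of modIVIg with vehicle. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.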

Results

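Gene expression was measured in liver, kidney and circulating white blood cells of male mice, 20 to 30 weeks old, given LPS, a bacterial endotoxin that sets off systemic inflammation. The mice also received vehicle, IVIg (pooled IgG for intravenous use) or modIVIg, a modified form whose modification the labels do not describe. Liver had 4 arrays per group. Kidney had 3 vehicle, 4 IVIg and 4 modIVIg arrays, and blood had 3 vehicle arrays, 3 IVIg arrays and 1 usable modIVIg array. No mouse without LPS was measured, so the values below compare treatments under LPS. The questions are whether either immunoglobulin alters the transcriptional response to LPS, and whether the modified form differs from IVIg.

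In liver, 352 of 7155 features passed between modIVIg with LPS and vehicle with LPS, 141 higher and 211 lower. Of 36 gene lists 18 passed at the preset correlation and 0 with an estimated correlation. Of all called genes with separate groups, Upp2 (uridine phosphorylase) fell most, with a log2 change of −3.17 ± 0.50 and 4 arrays per group. Rgs16 (−2.83 ± 0.63), Btc (betacellulin, −2.76 ± 0.56), Cmpk2 (−2.68 ± 0.52) and Rsad2 (viperin, −2.62 ± 0.61) followed. Adm (adrenomedullin) fell by 2.56, Keg1 by 2.41, Slc2a2 (the glucose transporter GLUT2) by 2.38, Hsd3b5 (a steroid-metabolising liver enzyme) by 2.35 and Hpgd (which degrades prostaglandins) by 2.35. The largest rises were Rnf138rt1 at 2.12 ± 0.24, Stbd1 (a glycogen-binding protein) at 1.64 ± 0.41, Plpp5 at 1.54 ± 0.30 and Gtf2ird1 at 1.53 ± 0.18. Foxa1, a liver transcription factor detected on none of the vehicle arrays, rose at least 1.09-fold (fitted log2 change 1.48). Creld2 and Pdia4, both induced by unfolded protein, rose by 1.38 and 1.33, Nupr1, a stress-induced nuclear protein, by 1.33, Tubb5 by 1.32 and Tceal9 by 1.31. As the rule for naming requires, all 20 of these genes had modIVIg arrays lying wholly above or below the vehicle arrays. Their adjusted p lay between 0.00136 (Rnf138rt1) and 0.0398 (Stbd1).

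**Figure D1:**
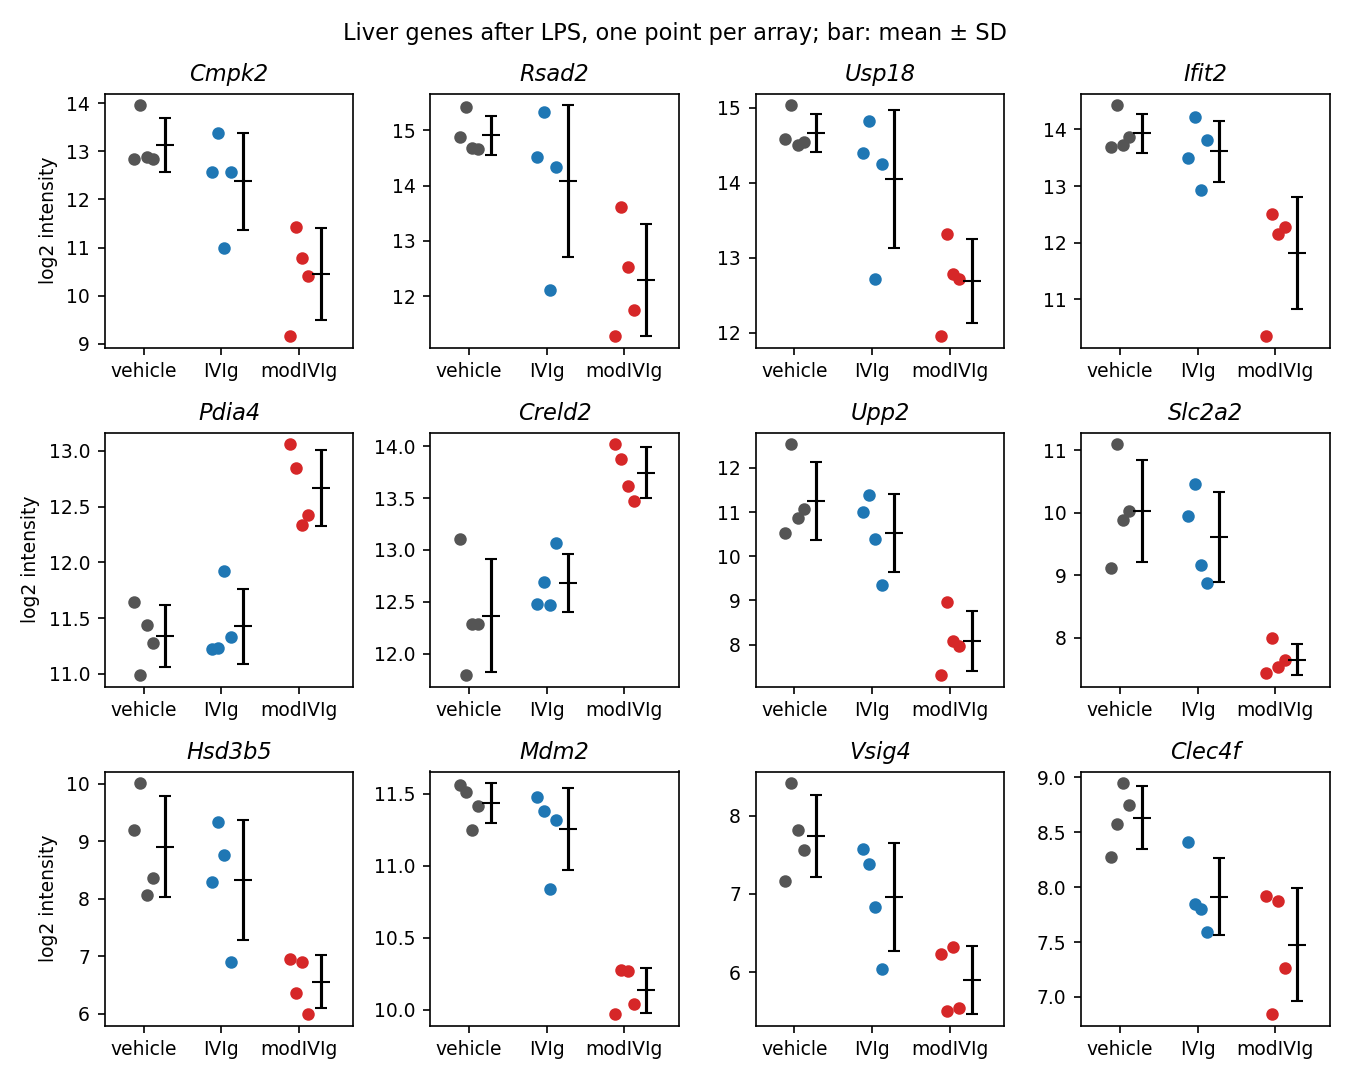
Log2 intensity of 12 liver genes, 1 point per array, in mice given LPS with vehicle, IVIg or modIVIg (4 arrays each); bars give the mean ± SD. Pdia4 lies between 12.34 and 13.06 on the modIVIg arrays and at or under 11.92 on all others, Slc2a2 is at or above 8.87 on the vehicle and IVIg arrays and lower on every modIVIg array, and Usp18 on IVIg replicate 3 (12.72) lies among the modIVIg arrays.

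Type I interferon-stimulated genes fell together in the modIVIg livers. Of 25 measured, 24 were lower, 10 passed over all genes and 16 passed when adjusted over the list alone, with a median log2 change of −0.76. Besides Cmpk2 and Rsad2 they include Ifit2 (−2.11 ± 0.42), Usp18 (−1.97 ± 0.39), Oasl1 (−1.94 ± 0.34) and Ifit3 (−1.20 ± 0.23), while Mx1 at −2.14 ± 0.60 passed over the list and not over all genes (adjusted p = 0.0577). The list's shift had adjusted p = 1.90e-11, and adjusted p = 0.263 with an estimated correlation. Kupffer cell markers were lower in the same livers: 4 of 9 fell over all genes and over the list alone, namely Vsig4 (−1.84 ± 0.35), Spic (−1.23 ± 0.27), Clec4f (−1.16 ± 0.25) and Timd4, which no modIVIg array detected and which was at least 1.35-fold lower. The Kupffer list had a median of −0.16 and adjusted p = 0.00625, or adjusted p = 0.312 with an estimated correlation. Cytokines and chemokines had a median of −0.41 (16 of 20 lower; adjusted p = 0.00458, and adjusted p = 0.446 with an estimated correlation). Among them the growth factor Csf1 fell by 0.83 ± 0.21, the 1 member to pass over all genes and also when adjusted over the list alone, and Tnf was at −1.03 ± 0.33 without passing (adjusted p = 0.0875). Genes of the NF-kB pathway had a median of −0.44 with 0 of 20 passing in limma over all genes or over the list alone (adjusted p = 0.00212 for the list, and adjusted p = 0.471 with an estimated correlation). All 6 MHC class II genes were lower, with a median of −0.61. Of them 0 passed over all genes and 5 adjusted over the list alone, H2-Ab1 (−0.68) and Cd74 (−0.70) among them. The list had adjusted p = 0.00184, or adjusted p = 0.263 with an estimated correlation. Of the immediate early genes 12 of 13 were lower, 0 passed over all genes and 2, Zfp36 at −1.35 and Fos at −1.40, passed adjusted over the list alone. Their median was −0.55 (adjusted p = 0.00279, and adjusted p = 0.445 with an estimated correlation). Irak2, a kinase of Toll-like receptor signalling, fell by 0.83 ± 0.20, although the TLR4 pathway list did not shift (median 0.10, adjusted p = 0.682).

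Endoplasmic reticulum stress genes were the 1 list that rose in this comparison. Of 19 measured, 6 rose over all genes and 11 adjusted over the list alone, with a median of 0.58. Pdia3 (0.62 ± 0.11), Hsp90b1 (0.76 ± 0.16) and Asns (1.06 ± 0.27) rose with Creld2 and Pdia4. The chaperone Hspa5 was at 0.58 ± 0.18 (adjusted p = 0.0846). The list had adjusted p = 0.00212, and adjusted p = 0.263 with an estimated correlation. Among p53 targets and apoptosis genes, 2 of 21 fell over all genes and 7 adjusted over the list alone, Mdm2 (the p53 ubiquitin ligase) by 1.30 ± 0.15 and Bbc3 by 1.09 ± 0.23. The list had a median of −0.49 and adjusted p = 9.34e-05, or adjusted p = 0.263 with an estimated correlation.

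Several metabolic lists shifted down in the modIVIg livers. In amino acid and urea metabolism 5 of 26 genes fell over all genes and 12 adjusted over the list alone, with a median of −0.40. Slc25a13 fell by 1.32 ± 0.27, Gpt by 0.94 ± 0.23 and Hpd by 0.70 ± 0.15, while Cps1 at −0.53 passed over the list only. In xenobiotic metabolism 5 of 22 fell over all genes and 8 adjusted over the list alone, with a median of −0.25. Fmo5 (−1.24 ± 0.28), Cyp2a5 (−1.14 ± 0.27) and Cyp1a2 (−0.72 ± 0.15) were among them. In gluconeogenesis and glycogen 4 of 17 fell over all genes and 5 adjusted over the list alone, with a median of −0.39. They include Gys2 (glycogen synthase, −1.32 ± 0.34), Pygl (glycogen phosphorylase, −0.78 ± 0.15) and Pck1 (−0.68 ± 0.16). The adjusted p values of the 3 lists were 5.67e-06, 0.000113 and 0.00307. None kept its call, with adjusted p = 0.246 with an estimated correlation for the first and the last and adjusted p = 0.263 with an estimated correlation for xenobiotic metabolism. Single members of other lists also fell: Bdh1, a ketone body enzyme, by 1.48 ± 0.19, the desaturase Fads2 by 1.21 ± 0.24, the bile salt pump Abcb11 by 0.87 ± 0.14, the phospholipid transporter Abcb4 by 0.70 ± 0.13 and prekallikrein (Klkb1) by 1.15 ± 0.17. Ehhadh (−1.11 ± 0.32) and Pdk4 (1.13 ± 0.31), in the fatty acid oxidation list, passed over that list and not over all genes. The endothelial genes Clec4g and Flt1 fell by 1.36 and 0.69. F8, C1qa and the red cell anion exchanger Slc4a1, each detected on none of the modIVIg arrays, were at least 1.49-fold, 1.39-fold and 2.34-fold lower. Ndrg1 rose by 1.23 ± 0.29. Acute phase proteins as a list did not shift (14 of 25 higher, median 0.01, adjusted p = 0.789), and 1 of them, Apcs, rose over all genes by 0.64 ± 0.17, with 2 rising adjusted over the list alone (Orm2 at 0.84). The hepatocyte marker list did not pass (median −0.06, adjusted p = 0.0513).

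The 352 features had a median absolute log2 change of 0.91. In 348 of them the groups did not overlap. Such separation was found in 19.8% of all tested features, where chance gives 2.86%. At least as many list calls as the real 18 came from 3 of the 35 ways to split these 8 arrays. With 1 array left out 15 to 18 of the list calls were kept, the fewest without modIVIg replicate 2. The gene count was 84 without vehicle replicate 2 and 84 without modIVIg replicate 1, and it was 813 without IVIg replicate 3, which enters only the shared spread. It was 142 and 150 without vehicle replicates 3 and 4, and 155, 110 and 129 without modIVIg replicates 2, 3 and 4.

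**Figure D2:**
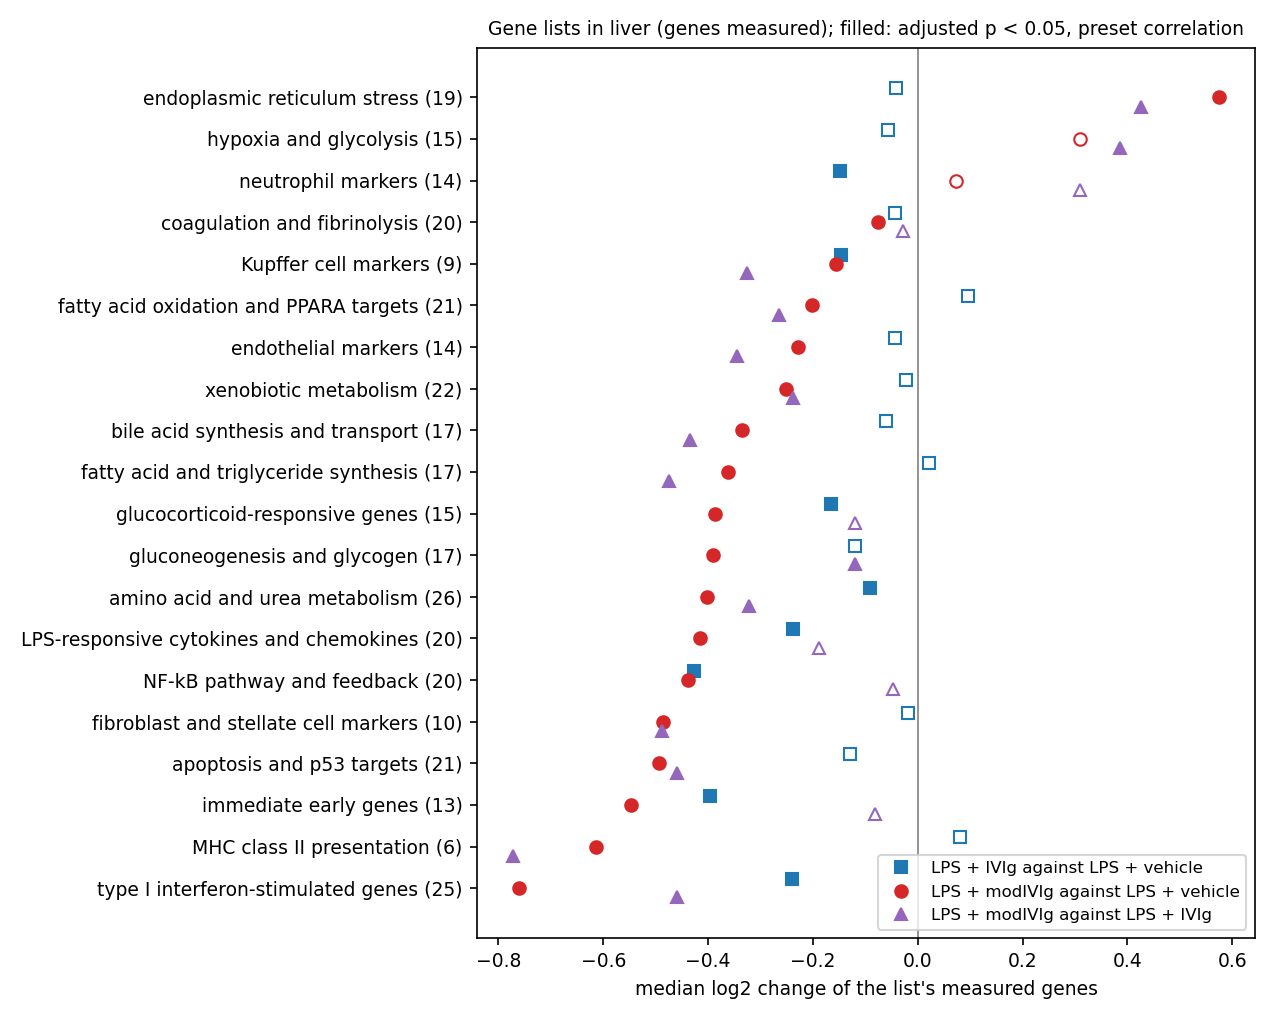
Median log2 change of the measured genes of each list that passed in at least 1 liver comparison (number of genes in brackets); squares, circles and triangles are the 3 comparisons, filled where adjusted p is under 0.05 at the preset correlation. Interferon-stimulated genes (median −0.76) and endoplasmic reticulum stress genes (0.58) lie at opposite ends for modIVIg against vehicle.

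Set against IVIg in liver, modIVIg lowered Upp2 by 2.45 ± 0.50, Spon2 by 2.28 ± 0.42, Gtse1 by 2.11 ± 0.36, Keg1 by 2.11 ± 0.44, Gm4952 by 2.05 ± 0.44 and Slc2a2 by 1.96 ± 0.40, again with 4 arrays per group. Bdh1 (−1.58), Acta2 (smooth muscle actin, −1.57), Phf11a (−1.53), Mdm2 (−1.12), Fads2 (−1.12), Klkb1 (−0.97) and Abcb4 (−0.69) also fell. Slc17a4 and Cyp2c55, detected on none of the modIVIg arrays, were at least 1.53-fold and 1.75-fold lower. Rises were led by Rnf138rt1 (1.93 ± 0.24), Nupr1 (1.29 ± 0.27), Tceal9 (1.25 ± 0.22) and Pdia4 (1.24 ± 0.21), followed by Fam50a (1.06), Gtf2ird1 (0.97), Zfp446 (0.89) and Pcgf6 (0.69). Coprs and Ccno, detected on none of the IVIg arrays, rose at least 1.55-fold and 1.11-fold. Adjusted p values ran from 0.00556 (Rnf138rt1, Bdh1) to 0.0481 (Fads2). Interferon-stimulated genes had a median of −0.46 with 0 of 25 passing in limma over all genes and 9 adjusted over the list alone. Ifit2 was at −1.79, Oasl1 at −1.47 and Ifit3 at −1.05 (list adjusted p = 6.59e-08, and adjusted p = 0.267 with an estimated correlation). The mean of the list did not pass an exact permutation test over the arrays (−0.69, p = 0.114, two-sided). MHC class II genes had a median of −0.77, with 0 of 6 passing over all genes and 4 adjusted over the list alone. H2-Aa was at −1.07 and H2-Eb1 at −0.87 (list adjusted p = 3.28e-05, and adjusted p = 0.218 with an estimated correlation). Endoplasmic reticulum stress genes had a median of 0.43, with 1 of 19 rising over all genes and 10 adjusted over the list alone (adjusted p = 0.000123, and adjusted p = 0.218 with an estimated correlation). Creld2 was at 1.07 (adjusted p = 0.056). Hypoxia and glycolysis genes had a median of 0.39, with 0 of 15 passing over all genes. Ndrg1 (1.05) and Pkm (1.03) passed adjusted over the list alone, 2 in all (list adjusted p = 0.0386, and adjusted p = 0.313 with an estimated correlation). Kupffer cell markers were lower here too (median −0.33; 0 of 9 over all genes and 2 adjusted over the list alone; adjusted p = 0.0455, and adjusted p = 0.453 with an estimated correlation).

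In this comparison 78 features passed, 14 higher and 64 lower, and in all 78 the groups did not overlap, a separation found in 9.64% of tested features against 2.86% by chance. Of the 78, 72 were also called in the same direction against vehicle, where independent lists would share 2.16 and unchanged groups with these modIVIg arrays in common share 21.2 of as many leading features (mean of 100 simulations). With the modIVIg arrays split between the comparisons, 52.3 of as many leading features were shared (mean of 6 splits, from 43 to 60). Of the 14 list calls here, 10 to 14 were kept with 1 array left out, the fewest without IVIg replicate 3. The count was 9, 15, 352 and 129 without IVIg replicates 1, 2, 3 and 4, and 12, 12, 16 and 13 without modIVIg replicates 1, 2, 3 and 4. It was 50, 38 and 34 without vehicle replicates 1, 3 and 4, which enter only the shared spread.

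Unmodified IVIg did not change any liver gene past the threshold against vehicle. Clec4f was at −0.72 ± 0.25, Vsig4 at −0.78 ± 0.35, Relb at −0.59 ± 0.30, Nfkbiz at −0.54 ± 0.30 and Egr2 at −0.70 ± 0.34, none of which passed (4 arrays per group, adjusted p = 0.999). The highest statistics were those of Mlec (0.45), Atoh8 (detected on none of the vehicle arrays and with a bound under 1, so no fold is given) and Fzd7 (0.83) and the lowest those of Elf3 (−0.67), Rpia (−0.52) and Prex2 (−0.65), again without passing. NF-kB pathway genes shifted down as a list with a median of −0.43 (19 of 20 lower; adjusted p = 6.67e-08, and adjusted p = 0.533 with an estimated correlation). Interferon-stimulated genes had a median of −0.24 (23 of 25 lower; adjusted p = 2.78e-06, and adjusted p = 0.533 with an estimated correlation), Usp18 being at −0.62 ± 0.39. Neutrophil markers (−0.15, with Ltf at −0.85), Kupffer cell markers (−0.15) and glucocorticoid-responsive genes (−0.17, with Mt2 at −0.51) shifted down with adjusted p = 0.0158 each, and adjusted p = 0.533 with an estimated correlation. Amino acid and urea metabolism (−0.09, with Tdo2 at −0.33) had adjusted p = 0.0175, and adjusted p = 0.533 with an estimated correlation. Immediate early genes (median −0.40; adjusted p = 0.000188, and adjusted p = 0.533 with an estimated correlation) and cytokines (median −0.24, with Cxcl1 at −0.36; adjusted p = 0.0158, and adjusted p = 0.62 with an estimated correlation) shifted down as well. Of these 8 list calls, 6 were lost without IVIg replicate 3, 5 without vehicle replicate 3, 3 without IVIg replicate 4, 2 without vehicle replicate 2 and 1 each without vehicle replicate 1 and IVIg replicate 2. Without IVIg replicate 3 the median of cytokines was 0.055, and that of immediate early genes −0.048 with the test pointing up. The mean of the interferon-stimulated genes did not pass an exact permutation test over the arrays (−0.31, p = 0.286, two-sided).

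With limma 0 of 7155 features passed, 128 had an unadjusted p under 0.05, and the groups did not overlap in 0.894% of features against 2.86% by chance. In these lists 0 members passed over all genes and 0 adjusted over the list alone. Of the 352 features called for modIVIg against vehicle, 306 (86.9%) had the same sign with IVIg. Simulations of unchanged groups sharing the vehicle arrays gave 90.9% for as many leading features. Those features lead by noise alone, part of it from the shared vehicle arrays, which favours the same sign. The simulated share is therefore no benchmark for the 352 if modIVIg changed them, and no conclusion is drawn from it. With the vehicle arrays split between the comparisons the share with the same sign was 68.7% (mean of 6 splits, from 56.3% to 83.0%). Across all liver features, which are not independent replicates, the changes by IVIg and by modIVIg correlated at 0.548 against 0.498 in simulations of unchanged groups that share the vehicle arrays. Their covariance was 0.0485 against 0.0254 simulated. With the vehicle arrays split between the comparisons, the correlation averaged 0.234 over 6 splits and the covariance 0.0256.

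In kidney no gene passed in limma in any comparison. Against vehicle, IVIg kidneys had lower adipocyte markers: all 9 were lower with a median of −1.48, and Cidec (a lipid droplet protein, −2.63 ± 0.68) and Adipoq (adiponectin, −3.08 ± 0.97) passed when adjusted over the list alone, while 0 passed over all genes and 0 of any other list named for this comparison passed adjusted over the list alone. The median was −0.90 within replicates 1 and 2 and −2.43 within replicates 3 and 4 (list adjusted p = 5.55e-11, and adjusted p = 0.162 with an estimated correlation). Vehicle replicate 3 is the only vehicle array in the second part, so every value against vehicle within replicates 3 and 4 rests on it. IVIg and modIVIg have replicates 3 and 4 there. Kidney comparisons with vehicle are therefore unbalanced over the split, and the fit without a block does not remove this. Acute phase proteins were lower in the same kidneys (16 of 18, median −0.35, adjusted p = 2.51e-09, and adjusted p = 0.252 with an estimated correlation). Their median was −0.01 within replicates 1 and 2 and −1.01 within replicates 3 and 4. Of these, Hp (haptoglobin) was at −2.40 ± 0.79 and Serpina3n at −1.47 ± 0.62. Fatty acid synthesis genes had a median of −0.14 with Scd1 at −1.67 ± 0.47 and Acaca at −1.52 ± 0.64 (adjusted p = 4.87e-05, and adjusted p = 0.284 with an estimated correlation; −0.20 and −0.23 within the parts). With the mean of the adipocyte markers of each kidney as a covariate, the acute phase and fatty acid synthesis lists did not pass (adjusted p = 0.157 and 0.237). That mean ran from 7.79 to 10.33 on vehicle, 6.52 to 7.84 on IVIg and 8.37 to 9.80 on modIVIg arrays. It is thus tied to treatment, and the covariate can remove part of a treatment difference. Calls lost or kept with it do not show what fat accounts for. MHC class II genes were higher with IVIg (7 of 9, median 0.41, adjusted p = 0.00326, and adjusted p = 0.284 with an estimated correlation; 0.45 and 0.52 within the parts), with H2-Eb1 at 0.53 ± 0.26 and H2-DMb1 at 0.50 ± 0.24. Monocyte and macrophage markers were also higher (median 0.22, adjusted p = 0.0427, and adjusted p = 0.252 with an estimated correlation; 0.40 and 0.18 within the parts), with Lst1 at 0.58 ± 0.25. Both kept the call with the adipocyte covariate (adjusted p = 2.84e-05 and 0.00928). The gene statistics were highest for Dcx, Dhx9 (0.48) and Fermt1 (0.78), and lowest for Cidec, Scd1 and Pank3 (−0.62). Dcx, detected on none of the vehicle arrays, was at least 1.06-fold higher.

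**Figure D3:**
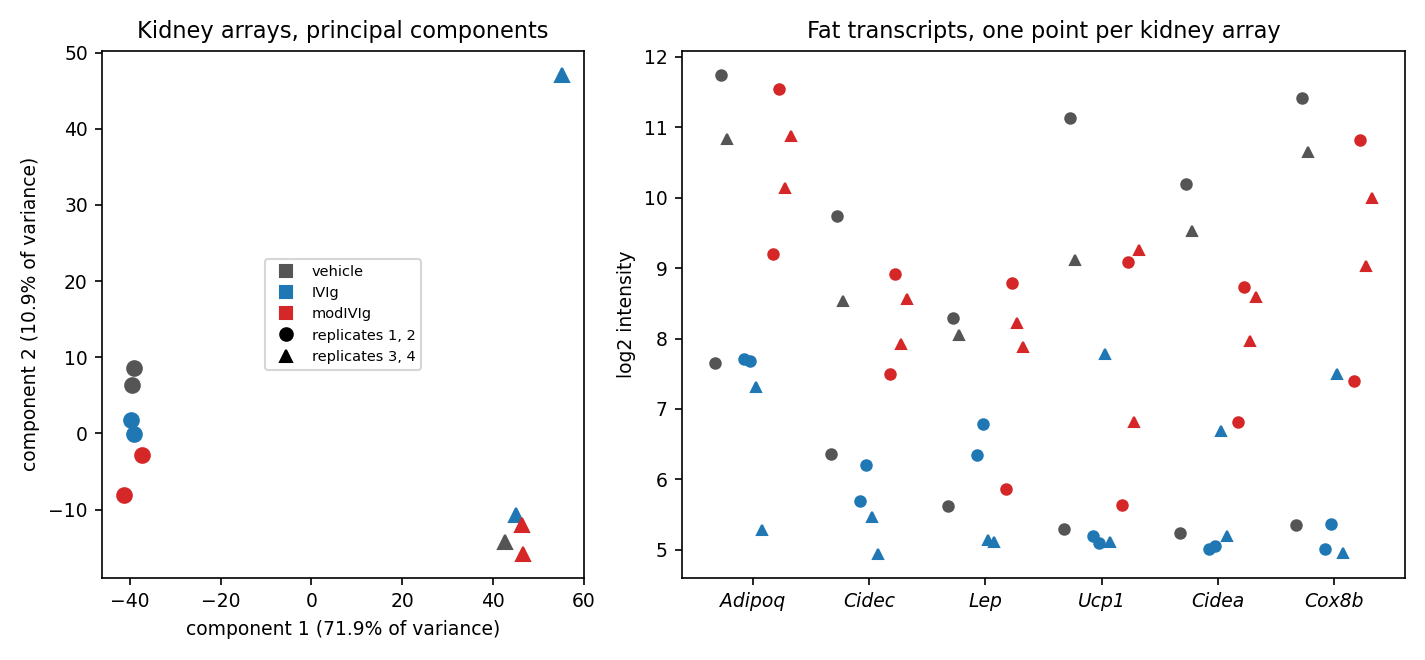
Left, the first 2 principal components of the 11 kidney arrays (71.9% and 10.9% of the variance), with replicates 1 and 2 (circles) apart from replicates 3 and 4 (triangles) in every treatment. Right, log2 intensity of 6 fat transcripts on each kidney array; Adipoq is at or under 7.71 on the 4 IVIg arrays and on vehicle replicate 1 (7.65), and at or above 9.21 on the other arrays.

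With modIVIg against vehicle, kidney interferon-stimulated genes were lower (20 of 25, median −0.19; −0.22 within replicates 1 and 2 and −0.25 within replicates 3 and 4). Cmpk2 (−0.68 ± 0.18) and Oasl1 (−0.84 ± 0.22) passed adjusted over the list alone, 0 passed over all genes, and the list had adjusted p = 6.54e-05, or adjusted p = 0.33 with an estimated correlation. Proximal tubule transporters (19 of 22 lower, median −0.25) included the amino acid transporter Slc6a19 at −0.63 ± 0.25 (list adjusted p = 0.000136, and adjusted p = 0.277 with an estimated correlation). The list median lay outside the −0.19 and −0.04 found within the parts, in a comparison unbalanced over the split. Genes of the loop, distal tubule and collecting duct (19 of 23 lower, median −0.18; −0.23 and −0.20 within the parts) included Slc4a1 at −1.12 ± 0.33 and Cldn10 at −0.59 ± 0.20 (adjusted p = 0.000433, and adjusted p = 0.277 with an estimated correlation). Cholesterol synthesis genes had a median of −0.17 (−0.23 and −0.11 within the parts) with Hmgcs1 at −0.46 ± 0.19 (adjusted p = 0.0146, and adjusted p = 0.317 with an estimated correlation). Neutrophil markers were higher (11 of 12, median 0.33; 0.50 and 0.35 within the parts), Chil3 at 0.77 ± 0.26 and S100a8 at 0.76 ± 0.28 (adjusted p = 0.00075, and adjusted p = 0.33 with an estimated correlation). In the lists other than the interferon list 0 members passed adjusted over the list alone. Single genes with the highest statistics were Ltb4r1 (a leukotriene receptor, 1.21 ± 0.28), Uck2 (0.75) and Nudt18 (0.53), and the lowest were Scin (−1.38 ± 0.36), Cmpk2 and Oasl1, with adjusted p = 0.997.

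Between modIVIg and IVIg in kidney, adipocyte markers were higher with modIVIg (9 of 9, median 1.70; 1.10 and 1.59 within the parts; adjusted p = 5.08e-07, and adjusted p = 0.173 with an estimated correlation), with Adipoq at 3.44 ± 0.90 and Cidec at 2.64 ± 0.63. Acute phase proteins were higher in 18 of 18 (median 0.73; 0.34 and 1.13 within the parts; adjusted p = 7.58e-11, and adjusted p = 0.173 with an estimated correlation), with Hp at 3.03 ± 0.73. Haem and iron genes had a median of 0.27 with Trf (transferrin) at 2.14 ± 0.59 (adjusted p = 0.00011, and adjusted p = 0.115 with an estimated correlation; 0.23 and 0.31 within the parts). With the adipocyte covariate the adjusted p was 0.0264 for acute phase proteins and 0.211 for haem and iron genes. MHC class II genes were lower with modIVIg (8 of 9, median −0.63; −0.83 and −0.33 within the parts; adjusted p = 3.88e-05, and adjusted p = 0.173 with an estimated correlation), with Cd74 at −0.86 ± 0.24 and H2-Eb1 at −0.79 ± 0.24. Distal tubule genes were lower in 21 of 23 (median −0.27; −0.29 and −0.27 within the parts; adjusted p = 1.01e-05, and adjusted p = 0.115 with an estimated correlation), with Slc4a1 at −1.73 ± 0.31 and Cldn10 at −0.81 ± 0.18. Proximal tubule transporters had a median of −0.22 with Slc22a12 at −0.49 ± 0.18 (adjusted p = 0.000339, and adjusted p = 0.173 with an estimated correlation; −0.12 and −0.24 within the parts). Kidney injury genes had a median of 0.09, with Havcr1 (KIM-1) at 1.82 ± 0.71 and Krt20 at 2.21 ± 0.87. Their call (adjusted p = 0.016, and adjusted p = 0.522 with an estimated correlation) was lost with the replicate block (adjusted p = 0.0592), and the median was −0.05 and 0.26 within the parts. Adjusted over the list alone, 2 genes each passed among adipocyte, haem and iron, MHC class II and distal tubule genes, 1 each among acute phase proteins and neutrophil markers (Chil3 at 0.87), and 0 among proximal tubule and kidney injury genes. The lowest adjusted p over all genes was 0.387, for Psat1 (serine synthesis, 0.90 ± 0.13). Nt5e (0.84) and Acat3 (1.11) had the next highest statistics among probes with a gene symbol, and Slc4a1, Cldn10 and Hdhd3 the lowest. Hdhd3, detected on none of the modIVIg arrays, was at least 1.36-fold lower.

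With limma 0 of 8544 kidney features passed in each comparison, and 116, 226 and 325 had an unadjusted p under 0.05 for IVIg against vehicle, modIVIg against vehicle and modIVIg against IVIg. The same tests passed 12, 7 and 16 of 36 lists, 0 of them with an estimated correlation, and 9, 5 and 12 of these kept the call with the split of the arrays as a block. With the adipocyte covariate 2, 7 and 5 were kept, the 5 being MHC class II, acute phase, proximal tubule, distal tubule and endothelial genes. With 1 array left out 6 to 12, 5 to 7 and 10 to 16 of the calls were kept. The fewest in both comparisons with IVIg came without IVIg replicate 3, and for modIVIg against IVIg without modIVIg replicate 2 as well.

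With the replicate number as a block, 11, 6 and 12 of these kidney list calls were kept. For IVIg against vehicle the glucocorticoid-responsive genes (median −0.15, adjusted p = 0.00938, and adjusted p = 0.284 with an estimated correlation) had adjusted p = 0.0524 with the block. For modIVIg against vehicle the NRF2 and antioxidant genes (median −0.19, adjusted p = 0.0146, and adjusted p = 0.33 with an estimated correlation) had 0.0687. Between modIVIg and IVIg the call was lost for kidney injury genes, for apoptosis genes (median 0.10, adjusted p = 0.0236, and adjusted p = 0.404 with an estimated correlation; 0.0857 with the block), for glucocorticoid-responsive genes (median 0.18, adjusted p = 0.0346, and adjusted p = 0.336 with an estimated correlation; 0.0820) and for endothelial markers (median −0.23, adjusted p = 0.0387, and adjusted p = 0.522 with an estimated correlation; 0.0857). The block added 3 calls for modIVIg against vehicle. They were heat shock proteins (adjusted p = 0.0493 with the block and 0.251 without), fatty acid and triglyceride synthesis (0.0154 and 0.0560) and monocyte and macrophage markers (0.00561 and 0.0560). Without the block their adjusted p with an estimated correlation was 0.615, 0.615 and 0.317, and an estimated correlation was not run with the block.

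In blood, cytokines and chemokines were lower with IVIg than with vehicle: 13 of 14 were lower with a median of −0.72, Ccl7 at −1.30 ± 0.46, Cxcl1 at −1.34 ± 0.60 and Ccl5 at −0.63 ± 0.34 (3 arrays per group; 0 members passed over all genes or adjusted over the list alone). The list had adjusted p = 9.70e-05, and adjusted p = 0.645 with an estimated correlation, and without vehicle replicate 2 its call was lost. The heart muscle transcripts Myl3 and Myl2, detected on none of the IVIg arrays, were at least 3.21-fold and 2.44-fold lower than with vehicle. Actc1 was likewise detected on no IVIg array, and its bound is under 1, so no fold is given. Smtn (1.14), Zbtb7a (0.92) and Cd22, at least 1.44-fold higher, had the highest statistics. None passed. On the lone modIVIg array neutrophil markers were higher than in the vehicle group (17 of 20, median 0.51, adjusted p = 0.00442, and adjusted p = 0.835 with an estimated correlation), with Cd177 at 1.48 ± 0.46 and Mrgpra2b at 1.99 ± 0.74. This call was lost without vehicle replicate 3. Against IVIg their median was 0.93 (18 of 20 higher, adjusted p = 1.67e-06, and adjusted p = 0.987 with an estimated correlation), with Cd177 at 1.40 ± 0.46 and Camp at 1.23 ± 0.61. With the blank modIVIg array kept in the fit both neutrophil calls were lost, the list medians were −1.60 and −1.49, and Cd177 (−0.96 and −1.04), Mrgpra2b (−0.29) and Camp (−1.86) changed sign. That array holds background only, so this fit cannot decide on the neutrophil markers. With the authors' values, which hold a column for that sample too, both calls were kept at the preset correlation. In both comparisons 0 members passed over all genes or adjusted over the list alone. Mef2b (detected on none of the vehicle arrays), Tst (2.60) and Cnksr2 (2.32) stood highest against vehicle and Cdkn1a (at least 1.19-fold lower), Cdc34 and Myl3 (at least 1.58-fold lower) lowest. Against IVIg, Mef2b (1.80), Neu3 (1.75) and Tst (1.94) stood highest, and P2ry1, Septin9 (at least 1.36-fold lower) and Cdkn1a lowest. The modIVIg array did not detect Cdc34 or P2ry1, whose bounds are under 1, and no fold is given for them. This array detected 8.09% of probes, the lowest share of the blood arrays used. None passed over all genes, and against vehicle Cdkn1a passed adjusted over the list alone in both lists that hold it (adjusted p = 0.0391 and 0.026). With limma 0 of 3975 features passed in each comparison, and 45, 336 and 172 had an unadjusted p under 0.05 for IVIg against vehicle, modIVIg against vehicle and modIVIg against IVIg. With the replicate block the counts of the modIVIg comparisons were 132 and 111.

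The response to modIVIg differed between organs for Plk2, a stress-induced kinase, and Mdm2. In liver Plk2 was at −1.59 and Mdm2 at −1.30, and in kidney at −0.14 and 0.05. With liver and kidney only, these 2 genes passed the test of the difference (adjusted p = 0.0022 and 0.0376), a setting chosen after the data were seen. It covered only the 3329 features kept in all 3 organs, so genes not kept in blood were not compared. Over the 3 organs 62 of 3329 features passed for modIVIg against vehicle, led by Mecr (blood 2.15, liver −0.23, kidney 0.03), Tst (blood 2.60, liver −0.12, kidney −0.22), Plk2 (blood 1.22), Cdc34 and Echdc2. The lone blood modIVIg array detected neither of the last pair, so no blood change is given for them. The blood values come from the lone modIVIg array. The count was 33, 39, 40, 37 and 40 without liver modIVIg replicate 1, liver vehicle replicates 1, 2 and 4, and liver modIVIg replicate 4, and 38 and 201 without blood vehicle replicates 1 and 3. For IVIg against vehicle limma passed 0 of 3329 features, with 90 at an unadjusted p under 0.05. There 18 passed without blood vehicle replicate 3, 3 without kidney vehicle replicate 1 and 1 without blood IVIg replicate 2.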

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

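The tests of detection on the liver arrays, of fat along with kidney and of chance within the parts of the kidney split were chosen after the results were seen, as was the fit of liver and kidney only; the others were planned. Among the named values, 280 groups of 4 arrays were searched for 1 array far from the other 3, and 26 (9.29%) had one, where chance gives about 1 group in 20. The value given for each gene is the gap from the outlying array to its nearest neighbour as a share of the group's range.

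In liver vehicle, replicate 2 was highest for the interferon-stimulated genes Cmpk2 (0.966), Oasl1 (0.881) and Usp18 (0.833). There replicate 3 was highest for Cyp1a2 (0.840), replicate 4 was highest for Nupr1 (0.922), and replicate 1 was lowest for H2-Ab1 (0.879). In liver IVIg, replicate 3 was lowest for Egr2 (0.946), Relb (0.886) and Nupr1 (0.858) and highest for Pdia4 (0.850). There replicate 1 was lowest for Fzd7 (0.837), replicate 2 was highest for Klkb1 (0.834) and replicate 4 was highest for Tceal9 (0.834). In liver modIVIg, replicate 2 was lowest for Clec4g (0.938), Pdia3 (0.872) and C1qa (0.835) and highest for Zfp36 (0.886). There replicate 1 was highest for Coprs (0.906) and lowest for Ifit2 (0.832), replicate 3 was highest for Adm (0.865) and replicate 4 was highest for Slc17a4 (0.860). In kidney IVIg, replicate 3 was highest for Cldn10 (0.935) and lowest for Serpina3n (0.851), and replicate 4 was lowest for Adipoq (0.837). In kidney modIVIg, replicate 1 was highest for Chil3 (0.938) and replicate 3 was lowest for S100a8 (0.852).

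The change with modIVIg against vehicle differed between liver, kidney and blood for 62 features. The adjusted p of the difference was 5.51e-05 for Mecr, 0.00109 for Tst, 0.00109 for Plk2, 0.00746 for Cdc34 and 0.00746 for Echdc2. Blood enters that test with 1 modIVIg array, so differences carried by blood rest on it. Mecr changed by 2.15 in blood, −0.23 in liver and 0.03 in kidney, and Tst by 2.60, −0.12 and −0.22. Mdm2 and Plk2 also differed with liver and kidney only (adjusted p = 0.0376 and 0.0022), and with the kidney split as a block as well (0.00417 and 4.30e-05). These fits compared only features that were kept in blood too. The authors' values for blood modIVIg replicate 2 correlated with those of the other blood arrays at a median of 0.954 across probes, which are not independent replicates, whereas the bead signals under that sample's name carried no signal over background.

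Interferon-stimulated genes were lower in modIVIg livers than in vehicle livers, with a mean log2 change over the 25 genes of −0.998 (SE 0.20), and Cmpk2, Oasl1 and Usp18 among them. A chance difference between the livers is argued against by an exact permutation test of the mean (p = 0.0286, two-sided, the smallest that 4 against 4 arrays can give). The same test gave 0.114 for modIVIg against IVIg and 0.286 for IVIg against vehicle. Lower signal on the modIVIg arrays is argued against by detection. The share of probes detected was 32.7% to 35.3% on modIVIg arrays and 31.6% to 33.9% on vehicle arrays. The highest modIVIg value lay 3.63 percentage points above the lowest vehicle value. Fewer Kupffer cells stay open, since the mean of the 9 Kupffer markers was lower by 0.52 (SE 0.16), carried by the 4 that fell (list median −0.16), and the interferon mean changed by a further −0.480 (SE 0.288), less than 2 SE. Monocyte and macrophage markers were at 0.01 (SE 0.26). A lower interferon response with modIVIg is a hypothesis that stays open beside the loss of Kupffer cells.

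Adipocyte markers were lower in IVIg kidneys than in vehicle kidneys, with Adipoq and Cidec in front. Fat taken along with some kidneys may account for this: 8 transcripts, made up of 6 of the 9 listed markers (Ucp1 of brown fat among them) and the brown fat transcripts Cidea and Cox8b, varied together within treatment groups (median pairwise correlation of deviations from group means 0.911, against at most 0.778 in 1000 random sets of 8), and Ucp1 ranged from 5.09 to 11.14 between kidneys. Over all 9 listed markers that median was 0.332, and 0.384 with the split of the arrays also removed. The 3 listed markers left out are Lpl, which every kidney array detects, Cd36, whose probe follows the split, and Pck1, for both reasons. Chance in which kidneys carried fat stays open. The permutation test and the adipocyte covariate used the mean of all 9 listed markers, the 3 left out above included. For IVIg against vehicle the exact permutation p of that mean was 0.0857 (two-sided) over all arrays. Within the parts of the split it was 0.167, where the smallest possible is 0.0556. For modIVIg against IVIg it was 0.0286 and 0.0556, each the smallest possible, so that over all arrays it argues against chance, but arrangements that keep the split cannot reach 0.05. An effect of IVIg on fat cells themselves was not tested.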

How the results depend on the processing

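The kidney batch block, the fits within kidney replicates, the adipocyte covariate, the blank array kept and the fits of liver and kidney only were chosen after the data were seen, and the other alternatives were planned. For modIVIg against vehicle in liver (352 genes), the count was 187 with no detection filter, 1112 with array weights (585 higher, 527 lower), 821 with only the 2 groups compared, 540 with the replicate block and 84 to 813 with 1 array left out. For modIVIg against IVIg in liver (78), it was 16 with no filter, 230 with array weights, 123 with trend and robust settings, 19 with only the 2 groups, 180 with the replicate block and 9 to 352 with 1 array left out. For blood modIVIg against vehicle (0), it was 77 with no filter, 182 with array weights and 132 with the replicate block, and against IVIg (0) it was 2 with joint normalisation, 463 with array weights and 111 with the replicate block. Organ differences for modIVIg (62) numbered 27 without background correction, 8 with the authors' values, 258 with no filter, 35 for probes detected on every array, 247 with joint normalisation, 564 with array weights, 162 with the kidney batch block, 315 with the blank array kept, 2 for liver and kidney only, 2 for these with the block, and 33 to 201 with 1 array left out; for IVIg (0) they numbered 0 to 18. The authors' values include a column for blood modIVIg replicate 2, which the main fit leaves out. Counts that involve blood therefore differ there in their samples as well as in the normalisation. The cause of the changes in the counts was not tested. The kidney counts, liver IVIg against vehicle and blood IVIg against vehicle stayed at 0 under every alternative run.

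In liver same-numbered arrays did not pair as a whole by the check (6 of 12 correlations over 0.1, from −0.130 to 0.521), nor in blood (2 of 3). In 3 liver pairs the closest partner had the same number, each time replicate 2 (0.521, 0.265 and 0.332). The 1 such pair in blood was replicate 2 as well (0.687). The kidney replicate block left the 3 gene counts at 0. Over all organs 71 of 78 list calls were kept with the replicate block, 75 without background correction, 77 with the authors' values and 0 with an estimated correlation; 26 of 35 kidney list calls were kept with the kidney batch block and 14 with the adipocyte covariate, which by its construction removes the 2 calls of the adipocyte list itself. List shifts whose test turned, with the cause not tested, had these medians. With 1 array left out, cytokines for IVIg against vehicle in liver ran from −0.46 to 0.055 (without IVIg replicate 3) and immediate early genes from −0.57 to −0.048 (without the same array, where the test turned up). For kidney IVIg against vehicle within replicates 1 and 2, NF-kB genes were at 0.11, interferon-stimulated genes at 0.073, acute phase proteins at −0.014 (the test turned up), immediate early genes at 0.29 and glucocorticoid-responsive genes at 0.044. With 1 array left out the highest medians, all without kidney IVIg replicate 3, and the lowest were 0.11 and −0.48 for NF-kB genes, 0.022 and −0.13 for interferon-stimulated genes, and 0.29 and −0.52 for immediate early genes. For kidney modIVIg against IVIg, immediate early genes were at −0.19 within replicates 1 and 2 and ran from −0.16 (without IVIg replicate 3) to 0.65 with 1 array left out, interferon-stimulated genes were at 0.061 within replicates 3 and 4, and glucocorticoid-responsive genes at 0.040 with the adipocyte covariate, where the test turned down. Medians alone changed sign, with the call lost, for blood neutrophil markers with the blank array kept (−1.60 and −1.49), for liver glucocorticoid-responsive genes for IVIg against vehicle without IVIg replicate 3 (0.0078), and in kidney without IVIg replicate 3 for glucocorticoid-responsive genes (0.020 against vehicle, −0.089 for modIVIg against IVIg) and kidney injury genes (−0.048). Within kidney replicates 1 and 2 the last pair were at −0.075 and −0.050 for modIVIg against IVIg. Of the named liver genes none reversed. With no detection filter 25 lost the call for modIVIg against vehicle and 20 for modIVIg against IVIg. The named genes were 71 and 33, and some of them had no call to lose. With only the 2 groups compared 0 and 19 lost the call, and with the authors' values 6 and 10. No slide block was run, because the files name no slides, and leaving out blood modIVIg replicate 1 leaves no group. Signal over background limits blood most, with 8.09% to 18.7% of probes detected.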

Other observations

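The tests on the split of the kidney arrays were chosen after it was seen; the splits of the arrays into other groups were planned. Further gene groups moved with modIVIg in liver. Fibroblast and stellate cell markers were lower against vehicle (9 of 10, median −0.49, adjusted p = 0.00866, and adjusted p = 0.4 with an estimated correlation; 0 passed over all genes and 2 adjusted over the list alone, Reln at −0.78 among them). They were lower against IVIg as well (median −0.49, adjusted p = 0.00184, and adjusted p = 0.312 with an estimated correlation; 1, Acta2, over all genes and 5 adjusted over the list alone). Fatty acid oxidation genes (18 of 21 lower, median −0.20, adjusted p = 0.00227), fatty acid and triglyceride synthesis genes (14 of 17 lower, median −0.36, adjusted p = 0.00307) and bile acid genes (11 of 17 lower, median −0.34, adjusted p = 0.0102) shifted down against vehicle, each with adjusted p = 0.263 with an estimated correlation. Endothelial markers (median −0.23, adjusted p = 0.011, and adjusted p = 0.42 with an estimated correlation) and glucocorticoid-responsive genes (median −0.39, adjusted p = 0.00733, and adjusted p = 0.272 with an estimated correlation) shifted down too. Interferon-gamma response genes did not shift (11 of 20 higher, median 0.06, adjusted p = 0.98). Of the NRF2 and antioxidant genes, whose list did not pass (adjusted p = 0.0917), Gstm4 fell by 1.32 ± 0.34 and Srxn1 was at 1.23 ± 0.35 (adjusted p = 0.0596).

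In kidney, heat shock proteins were lower with IVIg than with vehicle (10 of 12, median −0.19, adjusted p = 0.00834, and adjusted p = 0.252 with an estimated correlation), with adjusted p = 0.703 under the adipocyte covariate. Coagulation genes were higher (11 of 12, median 0.19, adjusted p = 0.00834, and adjusted p = 0.252 with an estimated correlation), with adjusted p = 0.157 under that covariate. NF-kB genes had a median of −0.33 (adjusted p = 0.000456, and adjusted p = 0.558 with an estimated correlation), with 0.11 within replicates 1 and 2 and −0.85 within replicates 3 and 4, and adjusted p = 0.432 under the covariate. Between modIVIg and IVIg, podocyte markers were lower in 6 of 6 (median −0.39, adjusted p = 0.00691, and adjusted p = 0.327 with an estimated correlation; −0.27 and −0.34 within the parts; adjusted p = 0.0564 under the covariate). Immediate early genes were higher in 14 of 14 (median 0.41, adjusted p = 0.00669, and adjusted p = 0.522 with an estimated correlation), with −0.19 within replicates 1 and 2 and 1.04 within replicates 3 and 4, and adjusted p = 0.162 under the covariate. Without IVIg replicate 3 the medians of the NF-kB genes and of the immediate early genes changed sign in these comparisons. That array stood apart on the second principal component of the kidney arrays (47.1, next highest 8.56). With limma 0 members of these kidney lists passed over all genes or adjusted over the list alone.

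Other splits of the same arrays were fitted to ask how often chance gives as much. For modIVIg in liver the splits argue against chance for the gene counts: 1 of 35 splits, the real one, gave 352 genes against vehicle (highest other 0). A share of 1 in 35 is the smallest these arrays can give, and it was not adjusted for the number of comparisons, so chance is not excluded. Against IVIg 1 of 35 gave 78 (highest other 22). The result against IVIg rests on the count past the threshold. The split that exchanges modIVIg replicate 2 with IVIg replicate 3 had more features at an unadjusted p under 0.05 in limma (1394 against 1173). The real count was 9 without IVIg replicate 1. The list counts do not argue against chance, with 3 of 35 splits reaching 18 lists against vehicle (highest other 20) and 3 of 35 reaching 14 against IVIg (highest other 16). For IVIg against vehicle in liver 23 of 35 splits reached the real 8 lists (highest other 16), so chance is not excluded. A real count of 0 genes is reached by every split and so tests nothing. This holds for IVIg against vehicle in liver (35 of 35, highest other 1), the 3 kidney comparisons (35 of 35 each), blood (10 of 10, highest other 279) and the organ differences with IVIg (100 of 100 regroupings, highest other 1326). In kidney 1496, 1365 and 3296 genes were called in the highest others, which part replicates 1 and 2 from replicates 3 and 4 and so point to a structure of the arrays. With that structure as a block the real counts stayed at 0. Kidney list counts were reached by 18, 9 and 3 of 35 splits (real 12, 7 and 16; highest other 18, 14 and 18), and by 5, 3 and 2 of the 8 splits that part as many same-numbered pairs as the real one, so chance is not excluded. The remaining splits part fewer numbers. In blood the 10 splits are too few for a share under 0.05: 8 reached the real 1 list (highest other 5). With 1 array left out the list count for IVIg against vehicle ran from 0 (without vehicle replicate 2) to 9 (without vehicle replicate 1).

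Kidney arrays of replicates 3 and 4 stood apart from those of replicates 1 and 2 in every treatment: 325 of 11010 kept probes (2.95%) were over 3 log2 units lower in replicates 3 and 4, with a median of −3.82, and 0 were as much higher. Lower abundance of these transcripts is argued against by other probes of the same genes, which changed by a median of 0.0911 for 111 lower probes of 106 genes (95% bootstrap interval −0.03 to 0.18). It stays open for the 21 (18.9%) whose other probe fell by over 1 log2 unit, 8 of them lower probes themselves. Lypla1 was at −5.92 on 1 probe and 0.34 on the other, and Cycs at −5.02 and −0.01. A labelling or hybridisation batch acting on single probes may be the source, and the blood minus liver difference of the same probes lay below that of their partner probes, with a median of −0.956 (interval −1.32 to −0.52; 0.04 in 1163 control pairs), which leaves it open because the interval spans the bound of −1 set for the test. No other biological explanation was tested. None of the 35 kidney genes checked, those named for a treatment difference, moved by more than 0.6 log2 units with the split. They were named from a fit without the split, where probes that move far with it have a wide spread and are less likely to be named. The check does not cover other members of the kidney lists. Among the adipocyte markers, Pck1 moved by −4.08 and Cd36 by −1.55.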
